A study of Mus musculus with 6 samples.

How the data were processed

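Total RNA from fibroblasts of wild-type and Prdm5 knockout mouse embryos was labelled and hybridised to Affymetrix Gene 1.0 ST arrays, with 3 arrays per genotype. The labels' protocols name a 3' IVT labelling kit, while the arrays carry probes along whole transcripts. They describe 3 littermate pairs but do not say which arrays form a pair. The deposited values are log2 intensities made with RMA, per the submitters' processing notes. The software version, annotation and genome build were not given in the sources used here. RMA subtracts background, forces the arrays to a shared distribution and summarises the probes of a set, so a shift common to most transcripts of an array would be removed.

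The deposited table held 34760 probe sets. A platform table gave 1 gene symbol for 21640, several for 1321 and no gene for 11799, which are unnamed here. Of the probe sets with 1 symbol, 21553 had an Entrez ID in the RefSeq table of mouse assembly GRCm38.p6, and 0 symbols needed an update. The build behind the array annotation was not given. That table was therefore used only for names and kinds of gene, gene spans, and order and distance along a chromosome. No coordinates are given. Probe sets of exactly 1 gene were kept, and the brightest over all arrays stood for each of 954 genes that had more than 1, which left 19937 genes. Several probe sets of a gene passed in one direction for 112 genes and in opposite directions for 5. No filter on dim genes was applied.

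Knockout was compared with wild type by lmFit and eBayes with a variance trend in limma 3.58.1 under R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Tables and figures were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The labels do not state whether arrays of one genotype came from separate embryos beyond the mention of littermate pairs, so p-values measure the spread between these arrays. Fixed before the data were examined were the design, the alternatives and 36 gene lists with 648 entries, of which 597 were measured. Lists were tested with camera at a preset correlation of 0.01, and with an estimated correlation, on ranks and with fry as checks. With an estimated correlation camera also draws its degrees of freedom from the 6 arrays rather than from the genes, which raises its p-values. The window around Prdm5 was 25 Mb, tested with Fisher's exact test on genes with p under 0.01.

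Most named genes were chosen by a rule fixed in advance. It takes Prdm5 and Mgll, then the 12 largest rises and 12 largest falls past the threshold whose groups do not overlap. It then takes the 4 members of smallest p in each list past the threshold and 2 in each other list, and the 4 of smallest p near Prdm5. Predicted genes, Riken clones and olfactory receptors were passed over, 66 of them among the calls. Prdm5 was not analysed here, since no named probe set carried its symbol. Dlk1, Rtl1, Dio3, Rian, Mir341, Mir376a, Mir376c, Mir379, Mir666, Mir667, Ndufb11, Sema3c, Lamc1, Mt1 and Mt2 were named after their values were seen.

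The procedure was tested on simulated data for the comparison of knockout with wild type, with 200 of 19937 genes changed. At a log2 change of 0.25 it recovered 44% with 4 false calls, at 0.5 it recovered 99% with 17, and at 1 it recovered 100% with 18. With no list changed, camera called 0 lists at 0.25 and at 0.5, and 1 list at 1. The simulated noise was independent between genes and arrays, so it does not show the error rate where genes vary together. In the data 2610 genes were called. The adjusted threshold depends on the share of changed genes, so the recovered percentages need not hold there. Alternatives covered the replicate number as a fixed or random block, a second quantile normalization, equal array medians, filters on the lowest 30% and 50% of genes, other variance models, array weights, the mean of a gene's probe sets, other thresholds and windows, and each array left out in turn. Added after the data were seen was the removal of each array's trend with gene span, by a spline of 4 degrees of freedom. It was first fitted as 1 curve over all genes and then, because that left a trend among brighter genes, apart in the brighter and dimmer 50%, and both versions are reported.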

Results

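Transcript levels were measured in mouse embryonic fibroblasts, connective tissue cells grown out of whole embryos, that carried either 2 wild-type copies of Prdm5 or LacZ-targeted copies alone (Prdm5 knockout). Prdm5 encodes a zinc-finger protein of the PRDM family. Embryos were taken at day 13.5 and cells were harvested at passage 3, with 3 arrays per genotype and 6 arrays in all. Median log2 levels over all probe sets lay between 7.10 and 7.16 on the 6 arrays. Array-to-array correlations across probe sets were 0.9945 to 0.9955 within a genotype and 0.9905 to 0.9936 between genotypes. The number of arrays limits the precision. The transcript of the targeted gene was not analysed here, because none of the named probe sets carried the symbol Prdm5, so the genotype labels could not be checked through it.

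The title of the series names monoacylglycerol lipase, the enzyme that splits monoacylglycerols such as the endocannabinoid 2-arachidonoylglycerol, so its gene Mgll was read first. Mgll was higher in knockout cells, at 9.70 ± 0.045 (SD, n = 3) against 8.61 ± 0.062 (SD, n = 3) in wild type. The log2 difference was 1.09 with a standard error of 0.054, a 2.14-fold rise, with an adjusted p of 3.70e-08 in limma. All 3 knockout values lay above all 3 wild-type values. An exact two-sided permutation test gave p = 0.1, the smallest that 20 assignments of 3 against 3 allow. Among 12 measured genes of monoacylglycerol and endocannabinoid metabolism, Mgll rose, Naaa, an acid amidase for N-acylethanolamines, fell (log2 -0.38, adjusted p 2.94e-05), and 10 did not pass. The same 2 passed when adjusted over the list alone, and the list as a group did not pass (adjusted p 0.819).

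**Figure D1:**
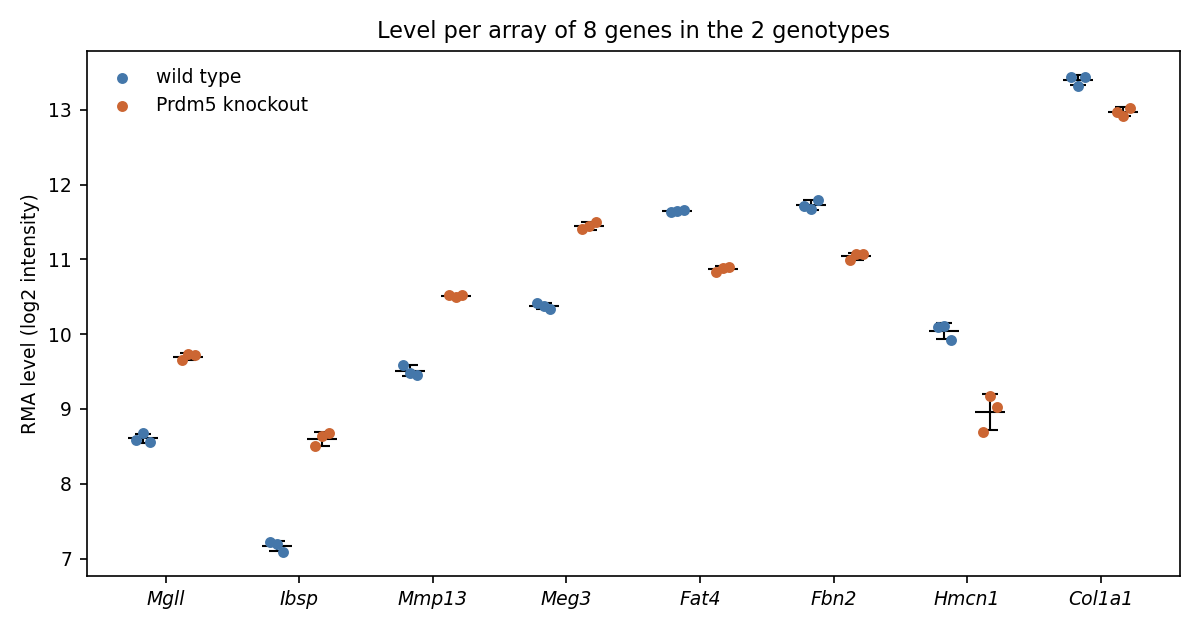
Log2 RMA level (vertical axis) of 8 genes on each array, with points for the 3 wild-type and the 3 knockout arrays and bars for the mean and SD. Mgll, Ibsp, Mmp13 and Meg3 lay higher and Fat4, Fbn2, Hmcn1 and Col1a1 lower on all 3 knockout arrays.

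Across the genome the knockout cells showed many small differences and few large ones. Of 19937 genes tested with limma, 1531 were higher and 1079 lower in knockout at an adjusted p under 0.05. Differences of at least 2-fold were found for 14 of the rises and 1 of the falls, whereas 1465 rises and 1055 falls were under 1.5-fold. The median size of a called difference was 0.25 on the log2 scale. The groups did not overlap for 6084 genes (30.5%), where chance gives 10%. Rises made up 58.7% of the calls, and 45.1% once the values were quantile normalized again. Without knockout replicate 3 the counts were 804 higher and 639 lower, and without wild type replicate 2 the count of lower genes was 693.

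Noncoding RNAs of the imprinted interval between Dlk1 and Dio3 led the rises. Mir300 rose by 1.97 on the log2 scale (standard error 0.072, 3.91-fold, adjusted p 4.75e-09), from 5.76 ± 0.026 to 7.73 ± 0.019 (SD, n = 3 each). Mir329 (1.68), Mir377 (1.66), Mir380 (1.53), Mir382 (1.53), Mir369 (1.45) and Mir323 (1.10) followed, with adjusted p from 2.13e-08 to 1.03e-04. The wild-type mean of Mir380, 4.96, lay below the lower quartile of every array (5.54 to 5.59). The size of its rise thus rests on a level not shown to be above background. Meg3, the long noncoding RNA of the same interval, rose by 1.08 (standard error 0.041, adjusted p 4.75e-09). Of 40 microRNA genes measured between Dlk1 and Dio3, 30 rose and 0 fell at this threshold in limma, and 31 and 0 had an unadjusted p under 0.05 in each direction. Some of the other rises also came from dim probe sets. The means over all 6 arrays of Mir376c (3.63), Mir376a (3.95) and Mir379 (4.25), among others, lay below those lower quartiles. The protein-coding genes of the interval did not pass, with log2 differences of 0.03 for Dlk1, 0.22 for Rtl1 and -0.03 for Dio3. With the gene length trend removed, Rtl1 passed as higher (log2 0.27, adjusted p 0.0207) and Mir666 as lower (-0.25, adjusted p 0.0151), while Mir341 and Mir667 no longer passed. Probe sets for microRNA genes can read host or precursor transcripts, so these differences are not a measurement of mature microRNAs.

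**Figure D2:**
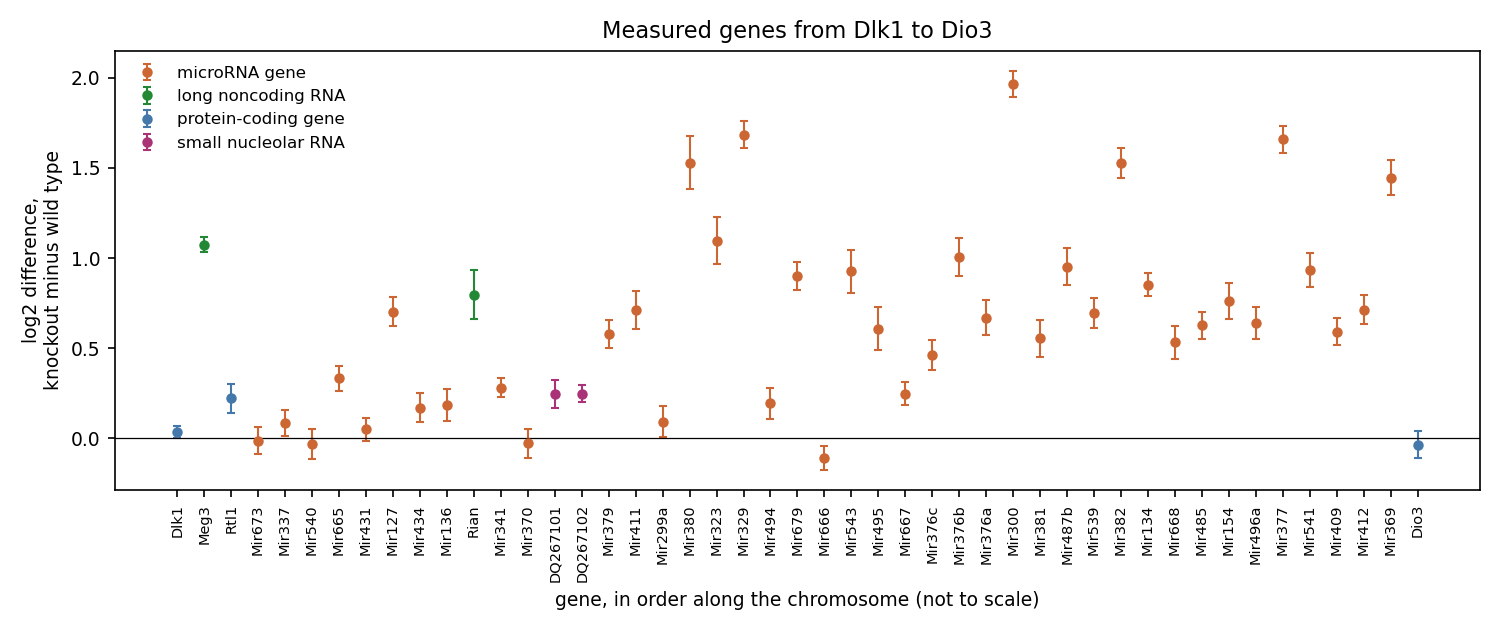
Log2 difference, knockout minus wild type, with its standard error, for each measured gene from Dlk1 to Dio3 in chromosome order (horizontal axis, not to scale), coloured by kind of gene. Meg3 and 30 of 40 microRNA genes passed the threshold as higher, while Dlk1, Rtl1 and Dio3 did not pass.

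Outside that interval, the largest rises included Ibsp, bone sialoprotein, at 1.43 (standard error 0.071, adjusted p 3.70e-08), Mir145a at 1.20 and Mir181b-1 at 1.17. The largest fall was that of Hmcn1, which encodes the extracellular protein hemicentin, with a log2 difference of -1.08 (standard error 0.095, adjusted p 9.11e-06). Hmcn1 is listed with 77 probe sets, of which the brightest was used. Slc26a7 (-0.85), Herc6 (-0.83), Tenm1 (-0.83), the desmosomal gene Dsp (-0.82) and the atypical cadherin Fat4 (-0.77) were also lower. The remaining falls of this size were in Rnu3a (-0.74), the integrin subunit Itga2 (-0.72), Nbeal1 (-0.70), the semaphorin Sema3d (-0.70), Niban1 (-0.69) and the microfibril gene Fbn2 (-0.69), with adjusted p from 2.92e-08 to 3.18e-04 over these 12 falls.

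More collagen genes fell than rose in knockout cells. Of 11 fibrillar collagen genes, which encode the main tensile fibres of connective tissue, 7 fell, 0 rose and 4 did not pass in limma, and 10 passed when adjusted over the list alone. Col1a1 fell from 13.40 ± 0.068 to 12.97 ± 0.056 (SD, n = 3 each), a log2 difference of -0.43 with an adjusted p of 1.07e-05. Col11a1 (-0.39), Col1a2 (-0.35) and Col3a1 (-0.24) were lower as well. Of 15 other collagens, 8 fell, 1 rose and 6 did not pass, with 14 adjusted over the list alone. The microfibrillar collagens Col6a3 (-0.47) and Col6a1 (-0.34), the growth plate collagen Col10a1 (-0.45) and Col12a1 (-0.26) were among those that fell. In camera the fibrillar list passed at an adjusted p of 3.27e-07, which was 0.527 with an estimated correlation. The other collagens passed at 1.71e-07, with an adjusted p of 0.0716 with an estimated correlation.

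The cholesterol synthesis genes that passed the threshold were all higher in knockout cells. Of 16 measured members, 9 rose, 0 fell and 7 did not pass in limma, and 10 passed when adjusted over the list alone. Fdft1, squalene synthase, rose by 0.44 (adjusted p 9.17e-06), Insig1, a sterol sensor, by 0.39, Idi1 by 0.33 and Sc5d by 0.25. The camera adjusted p was 1.71e-07, and the adjusted p was 0.0716 with an estimated correlation.

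Of the skeletal lists, osteoblast markers passed camera as higher and cartilage markers as lower. Of 10 osteoblast markers 3 rose, 0 fell and 7 did not pass, with 5 adjusted over the list alone. Ibsp led them, followed by alkaline phosphatase Alpl (0.36) and the homeobox gene Dlx5 (0.32), while Msx2 at 0.18 did not pass. Of 17 cartilage markers 5 fell, 2 rose and 10 did not pass, with 10 adjusted over the list alone. Comp (-0.49), Sox6 (-0.35) and Prg4 (-0.31) fell, whereas Chad rose by 0.41. The camera adjusted p was 0.0269 for osteoblast and 0.00357 for cartilage markers, and each had an adjusted p of 0.527 with an estimated correlation. The osteoblast list did not pass camera on ranks (adjusted p 0.263), its mean of 0.21 lying above its median of 0.10 with Ibsp at 1.43. The difference between these 2 lists was not itself tested.

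Contractile, inflammatory, Hox and mitotic lists also passed camera as higher, and each had an adjusted p of 0.527 with an estimated correlation. Of 13 smooth muscle and myofibroblast markers 5 rose and 8 did not pass, with 7 adjusted over the list alone. Calponin Cnn1 (0.21), Tpm2 (0.19), Actg2 (0.19) and Tagln (0.11) led them, and the list's adjusted p of 6.41e-05 became 0.0521 when the trend with gene length was removed. Of 20 inflammatory cytokines and NF-kB targets 4 rose and 16 did not pass, with 8 adjusted over the list alone (camera adjusted p 0.00238). These were the chemokine Cxcl12 (0.33), the cytokine Lif (0.49), Ptgs2 (0.18) and Icam1 (0.22). Of 37 Hox genes, which mark position along the body axis, 9 rose, 2 fell and 26 did not pass, with 15 adjusted over the list alone (camera adjusted p 0.00325). Hoxc5 (0.63), Hoxa3 (0.50), Hoxa5 (0.46) and Hoxc6 (0.45) rose, and the list had an adjusted p of 0.332 once the dimmest 50% of genes were left out. Of 21 mitosis genes 6 rose, 1 fell and 14 did not pass, with 8 adjusted over the list alone (camera adjusted p 0.0286). Cenpa (0.25), Kif23 (0.22) and Mad2l1 (0.20) rose and Top2a fell (-0.19), though the mean of the probe sets of Top2a gave -0.01. The mitosis list did not pass without wild type replicate 3 (adjusted p 0.128), knockout replicate 2 (0.0726) or knockout replicate 3 (0.0554). It also did not pass when quantile normalized again (0.077), with the lowest 30% (0.152) or 50% (0.379) of genes left out, or with the gene length trend removed (0.475). With an estimated correlation 0 of the 9 lists called by camera held, and 2 of 36 lists had an unadjusted p under 0.05. For cholesterol synthesis and other collagens the estimated correlations, -0.0217 and 0.00414, were under the preset 0.01. The rise of their adjusted p to 0.0716 in camera thus did not come from a larger correlation. With fry, which does not compare a list with other genes, 3 of the 9 passed, namely cholesterol synthesis, other collagens (adjusted p 0.000706 each) and osteoblast markers (0.0106), while fibrillar collagens had an adjusted p of 0.0563. Another split of the 6 arrays into 3 and 3, across genotypes, also called 9 lists with camera. That split still held part of the genotype difference.

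**Figure D3:**
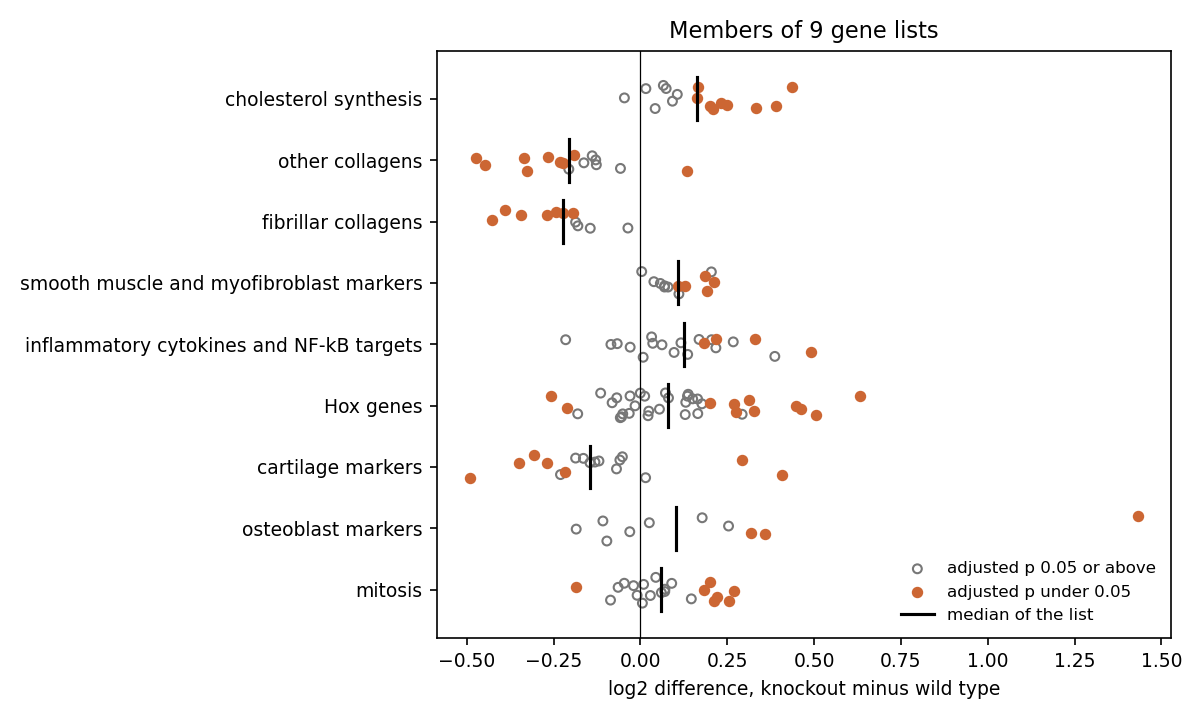
Log2 difference, knockout minus wild type (horizontal axis), of each measured member of the 9 gene lists that passed camera, with filled points for genes at an adjusted p under 0.05 and a bar at each list's median. The medians ran from -0.22 for fibrillar collagens to 0.16 for cholesterol synthesis.

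Other matrix lists held genes that went both ways. Of 23 elastic fibre and matrix glycoprotein genes 4 rose and 6 fell, with 11 adjusted over the list alone (adjusted p 0.822), and Fbln2 (-0.48) fell with Fbn2. Of 22 genes of collagen processing and cross-linking 5 rose and 5 fell, with 11 adjusted over the list alone (adjusted p 0.885), among them the lysyl hydroxylase Plod2 (0.40) and the prolyl hydroxylase P3h2 (-0.48). Matrix proteases and their inhibitors gave 4 rises and 2 falls among 20, with 8 adjusted over the list alone (adjusted p 0.514). The collagenase Mmp13 rose by 1.00 (standard error 0.048, adjusted p 2.92e-08) and Adamts9 fell (-0.52). Small leucine-rich proteoglycans gave 3 rises and 2 falls among 13, with 6 adjusted over the list alone (adjusted p 0.357), including Prelp (0.22) and decorin, Dcn (-0.23). Tendon and ligament markers gave 3 rises among 9, with 3 adjusted over the list alone (adjusted p 0.0838), led by Egr1 (0.21) and Egr2 (0.33), and the list passed without knockout replicate 1 (0.0371).

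The signalling and related lists that follow did not pass camera as groups with all 6 arrays and all genes. Among 25 Wnt ligands, receptors and antagonists 4 rose and 7 fell, with 12 adjusted over the list alone (adjusted p 0.33), and the receptors Fzd4 (-0.40) and Lrp6 (-0.31) fell. This list passed with fry (adjusted p 0.0353), and with camera once the dimmest 50% of genes were left out (0.0379). Among 17 Wnt target genes 1 rose and 2 fell, with 4 adjusted over the list alone (adjusted p 0.572), the antagonist Dkk1 falling (-0.56) and Myc rising (0.25). For 25 BMP and TGF-beta pathway genes the counts were 4 and 1, with 6 adjusted over the list alone (adjusted p 0.0867), and Id3 (0.28) and Id1 (0.23) rose. That list passed without wild type replicate 1 (0.0382) and without knockout replicate 2 (0.0256). For 15 p53 targets and senescence genes they were 4 and 2, with 7 adjusted over the list alone (adjusted p 0.38), including Plk2 (0.25) and Phlda3 (0.20). The unfolded protein response gave 3 rises and 1 fall among 16, with 5 adjusted over the list alone (adjusted p 0.385), Trib3 falling (-0.38) and Manf rising (0.31). Of 19 interferon response genes 0 passed in limma, overall or adjusted over the list alone (adjusted p 0.426), and 1 was lower at an unadjusted p under 0.05, with Ifit2 at -0.30 and Ifit1 at -0.19. Of 19 S phase and replication genes 1 rose and 1 fell, with 1 adjusted over the list alone (adjusted p 0.33), namely Tyms (0.23) and Mcm5 (-0.17).

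The metabolic and regulatory lists that follow did not pass camera as groups, and each held genes that rose and genes that fell. Fatty acid synthesis and uptake gave 4 rises and 3 falls among 17, with 9 adjusted over the list alone (adjusted p 0.885), and Acaca (-0.27) and Fasn (-0.22) fell. Hypoxia and glycolysis gave 1 rise, Tpi1 (0.20), and 1 fall, Hk2 (-0.26), among 16, with 2 adjusted over the list alone (adjusted p 0.788). The 18 imprinted genes gave 4 rises and 3 falls, with 7 adjusted over the list alone (adjusted p 0.598), Peg10 falling (-0.40) while Meg3 rose. The 26 positional and limb patterning genes gave 6 rises and 5 falls, with 14 adjusted over the list alone (adjusted p 0.841), led by Foxd1 (0.71) and Alx1 (0.50). Chromatin and cohesin factors gave 1 rise, Hdac2 (0.20), and 1 fall, Polr2a (-0.30), among 10, with 2 adjusted over the list alone (adjusted p 0.572). Of 13 other PRDM family genes Prdm6 rose (0.31) and Prdm10 fell (-0.22), with 2 adjusted over the list alone (adjusted p 0.391).

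Markers of other cell types that an embryo digest could hold gave few calls. Endothelial markers gave 0 calls among 11 in limma, and 0 adjusted over the list alone (adjusted p 0.169), and 3 lower at an unadjusted p under 0.05, with Emcn at -0.29 and Tek at -0.19. Macrophage and blood markers gave 1 rise, Cd68 (0.33), among 15, with 1 adjusted over the list alone (adjusted p 0.519), and Laptm5 at -0.22 did not pass. Epithelial and keratinocyte markers gave 1 fall, Dsp, among 14, with 1 adjusted over the list alone (adjusted p 0.33), and Krt8 at -0.18 did not pass. Mesothelial markers gave 1 rise, Upk1b (0.40), and 1 fall, Msln (-0.22), among 8, with 3 adjusted over the list alone (camera adjusted p 0.38, fry 0.0353). Neural and glial markers gave 1 rise, Fabp7 (0.82), and 1 fall, Map2 (-0.25), among 16, with 2 adjusted over the list alone (adjusted p 0.999). Adipocyte markers gave 1 fall, Pparg (-0.19), among 13, with 1 adjusted over the list alone (adjusted p 0.742), and Scd1 at 0.11 did not pass. Skeletal muscle markers gave 1 fall, Tnnt3 (-0.20), among 18, with 0 adjusted over the list alone (adjusted p 0.819), and Myh8 at -0.27 did not pass. Sex-linked genes gave 1 rise, Eif2s3y (0.47), among 7, with 1 adjusted over the list alone (adjusted p 0.572), and Zfy1 at -0.21 did not pass. In 7 of the lists the median, the mean and the camera direction differed in sign: matrix proteases, imprinted genes, monoacylglycerol metabolism, positional genes, collagen processing, fatty acid synthesis, and neural markers.

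Genes near Prdm5 were compared with the rest, since a targeted allele carries flanking chromosome from the stem cells it was made in. Within 25 Mb of Prdm5, 63 of 424 genes (14.86%) had an unadjusted limma p under 0.01, against 2912 of 19428 other genes (14.99%). The odds ratio was 0.990 with a 95% interval of 0.743 to 1.30, and the two-sided Fisher's exact test gave p = 1. Against 675 genes farther along the chromosome, of which 99 (14.7%) passed, the odds ratio was 1.01 with p = 0.931 in the same exact test. The 4 genes of smallest p in the window were Mgll, the water channel gene Aqp1 (-0.62), Fkbp9 (-0.33) and Herc6.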

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

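These probe sets carry no gene name here and so entered no comparison of the report, and they were looked at after the data were seen. Probe set 10538811 was lower in knockout, with a log2 difference of -1.77, from 9.71 to 7.94 (n = 3 each, adjusted p 0.000227 in limma). Its number lies between those of genes in the Prdm5 window. Aqp1 (10538459), Fkbp9 (10538547) and Herc6 (10538590) lay 10.4, 8.9 and 8.11 Mb from Prdm5, and Mgll (10539894) 22.8 Mb. If numbers follow the chromosome, which was not tested, it would lie in or near that window and could read Prdm5. Which probe set reads Prdm5 is not known here. The fall is therefore read neither as a check of the genotype nor as a change in another gene. Probe set 10340357 was higher by 2.58, from 3.93 to 6.51 (adjusted p 0.00102 in limma). Of the 11799 probe sets with no gene listed, 591 were higher and 175 lower. The values in this section come from a separate limma fit and adjustment over all 34760 probe sets, so they do not compare directly with the main calls. Whether some of these, 10340357 included, are control probe sets of the array is not known here. Of the 1321 listed with several genes, 63 were higher and 14 lower.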

How the results depend on the processing

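The removal of the gene length trend, in both versions, was chosen after the data were seen. Mgll stayed higher and past the threshold in all settings run. Counts of higher and lower genes moved from 1531 and 1079 to 706 and 581 with no variance trend, and to 14 and 1 at 2-fold or more. With array medians set equal 1003 genes were higher, and quantile normalized again 1665 were lower. Leaving out 1 array gave 804 to 1482 higher and 639 to 1157 lower genes. Knockout replicate 3 gave both lowest counts, and without wild type replicate 2 the lower count was 693. Removing the gene length trend gave 1341 higher and 1154 lower genes when fitted apart in brighter and dimmer genes, and 1597 and 788 with 1 curve over all genes, sharing 71.3% and 81.8% of the main calls. Called genes changed sign under 1 setting, the mean of a gene's probe sets, for 5 genes. Of the gene lists, 0 passed with an estimated correlation in camera (2 at an unadjusted p under 0.05) and 5 with fry, 3 of them among the 9 called by camera. On ranks the osteoblast markers were lost. In camera at the preset correlation, the mitosis list was lost under 7 of 18 settings of the values and arrays, Hox genes under 1 and smooth muscle markers under 1, and the other 6 under 0. For named genes other than Mgll, 54 values fell short of the threshold and 14 newly passed outside the leave-one-out settings, against 1228 that did neither, and leaving out 1 array gave 42, 5 and 613. The cause was not tested, except that leaving out an array lowers the number of samples. The Y-linked covariate was not run, since the Y-linked mean spanned 0.258 over the 6 arrays, and neither were the alternatives for Prdm5. Dim genes near background limit what these arrays can show.

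With the replicate number as a replicate block, 1370 genes were higher and 891 lower, sharing 83.5% of the main calls, and as a random effect 1269 and 875. Same-numbered arrays deviated together with correlations of -0.263, 0.119 and -0.209, and 1 of 6 arrays correlated best with its own number, so the numbers were not taken to pair arrays. The odds ratio near Prdm5 turned from 0.990 to 1.08 under the block (Fisher's exact test p = 0.565), on neither side past the threshold.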

Other observations

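Families picked by gene symbol after the data were seen added other groups, tested with camera at the preset correlation. The same arrays served to pick and to test them, and the adjustment covered only the 16 picked. Their p-values are thus descriptive and give no independent support. With an estimated correlation 0 of the 16 families passed, the adjusted p running from 0.159 to 0.659, and 4 had an unadjusted p under 0.05. Of 34 NADH dehydrogenase subunit genes, which encode parts of respiratory complex I, 12 rose and 0 fell in limma (camera adjusted p 9.15e-11, and adjusted p 0.317 with an estimated correlation), including Ndufb11 (log2 0.30). Of 77 mitochondrial ribosomal protein genes 17 rose and 0 fell (5.82e-08, and adjusted p 0.326 with an estimated correlation). Of 7 secreted semaphorins, which guide migrating cells and axons, 6 fell (1.37e-06, and adjusted p 0.159 with an estimated correlation), including Sema3d (-0.70) and Sema3c (-0.67). Of 10 laminins 3 fell (0.00156, and adjusted p 0.159 with an estimated correlation), Lamc1 by the most (-0.39). Of 4 metallothioneins 2 rose (0.00202, and adjusted p 0.159 with an estimated correlation), Mt2 by 0.89 and Mt1 by 0.58. Of 51 small nucleolar RNA genes 19 rose and 1 fell (1.2e-07). Cytosolic ribosomal protein genes and their paralogs gave 11 rises among 57 (7e-06), and proteasome subunits and assembly factors 9 among 39 (9.71e-05), and these last 3 groups each had an adjusted p of 0.317 with an estimated correlation. With the gene length trend removed, secreted semaphorins and complex I each had an adjusted p of 3.03e-05, metallothioneins 0.018, laminins 0.0222, mitochondrial ribosomal proteins 0.0381, small nucleolar RNA genes 0.169, proteasome genes 0.139, and cytosolic ribosomal proteins turned to lower at 0.501. A further 5 families passed camera and not with that trend removed, namely spliceosome proteins (0.000236, then 0.194), ADAMTS genes (0.00876, then 0.102), protocadherins and FAT cadherins (0.0206, then 0.486), cytochrome c oxidase subunits (0.0206, then 0.546) and IFITM genes (0.0276, then 0.0676). Transmembrane semaphorins (camera adjusted p 0.187), integrins (0.334) and the insulin-like growth factor system (0.433) did not pass, and the difference between secreted and transmembrane semaphorins was not tested.

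Of the tests that follow, only the counts of other splits were chosen before their result was seen, and the others were chosen after it. The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The genotype split called 2610 genes in limma and the highest other split 0, with 5303 and at most 1456 at an unadjusted p under 0.05, so 1 of 10 splits reached that count. For gene lists, 2 of 10 splits gave as many as the 9 of the genotype split, the highest other split also calling 9. That split set wild type replicate 1 with knockout replicates 1 and 3, and in it 0 genes passed in limma. Each other split sets 2 arrays of one genotype with 1 of the other. Part of the genotype difference thus stays in its contrast, and genotype widens the spread within its groups. The other splits are therefore not free of genotype, and their counts do not show what camera or limma call without it.

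Calls were more often falls among long genes and rises among short genes. Among genes in the brighter 50%, the shortest decile by span (median 2.54 kb) gave 253 rises and 17 falls among 996 (median log2 0.07), and the longest (median 198 kb) gave 51 and 269 (-0.08). A curve with gene span, common to genes of like span and brightness, is argued against as the whole cause of the calls. Of the called genes, 71.3% were still called in the same direction once it was removed. With 1 curve over all genes, which left the shortest decile at a median of 0.08, the share was 81.8%. The decile medians were small beside the median called difference of 0.25, so removing such a curve could leave most calls in place anyway. A length bias whose size differs between genes of like span was not tested. Span runs from the start to the end of a gene, introns included, so a bias that follows transcript length was not tested. Variation of the trend between arrays stays open, because the groups' mean slopes differed by 1.51 times the larger range within a group. RNA quality and labelling may produce such a slope, as may genotype, and these cannot be told apart here.

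Meg3 and 30 of 40 microRNA genes between Dlk1 and Dio3 rose while 10 did not pass, and Rian, another noncoding RNA of the interval, also rose (log2 0.80, adjusted p 0.00161 in limma). The median of 238 other microRNA genes was -2.26% of the interval's median of 0.63, with quartiles of -0.11 and 0.08. A rise of all microRNA probe sets is thus argued against. A floor at a mean log2 level of 3.625, that of Mir376c, chose these 238 out of 257. It lay below the lower quartile of every array (5.54 to 5.59), so some of them may be near background. A rise limited to expressed microRNA genes therefore stays open. Of these 238, 21 (8.82%) were called higher, against 7.68% of all genes, so some microRNA genes elsewhere rose too. A curve common to genes of like span is argued against as well, with 93.5% of 31 called genes of the interval still higher after its removal. A length bias particular to these genes was not tested. Genotype and a difference in imprinting between cultures were not tested and stay open.

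Mgll rose and lies 22.8 Mb from Prdm5. An effect of flanking chromosome on most genes near Prdm5 is argued against, since the upper bound of the odds ratio was 1.30. Within 10 Mb the bound was 1.63. Effects on a few genes of the window would hardly move such a share and stay open. A single strain variant at Mgll could still raise its level and was not tested, so a rise through loss of Prdm5 and one through a linked variant both stay open.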
